A study of Homo sapiens with 7 samples.

How the data were processed

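RNA sequencing libraries were compared between 3 samples given PBS and 4 samples given PTH (parathyroid hormone). The labels describe all 7 as LX2, an established human hepatic stellate cell line, and give the groups and the replicate numbers. The dose of PTH, the exposure time and whether the libraries came from separate cultures are not given in the sources used here.

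The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments) for every gene and library, in a table of 14913 rows and a table of 7149 rows split by the direction of change, per the file headers. Together they hold 22062 rows, all with rat Ensembl gene identifiers. Of these rows 8559 are at 0 in all libraries, more than the smaller table holds. The sizes of the tables are therefore not counts of genes that rose or fell. Bowtie 0.12.2 and the mouse build mm8 are named in the submitters' processing notes, and the series' design note speaks of mice. The program that made the FPKM values, its annotation release and any scaling between libraries are not given in the sources used here. The labels, the notes and the identifiers thus name different species, so genes carry their rat symbols, samples carry the names of their labels, and no genomic coordinates are given. The authors' group columns equalled the mean of the group's libraries within 1% except in 16 rows. The deposited fold changes are on a log2 scale in the table of lower genes, per the file headers. The column of the table of higher genes has the same heading and is read as a log2 fold change too, but since it holds 1 value outside the usual range of that scale the deposited column was checked only as a score. The authors also deposited a p-value and an FDR per gene, and 12285 rows have a p-value of 1, 943 of them with a mean of at least 1 FPKM, as if not tested.

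No read counts were used, so the test was made on log2(FPKM + 1). Where several rows share a symbol, the row with the highest mean was taken. Genes with a mean of at least 1 FPKM over the 7 libraries were tested, which left 10662. PTH was compared with PBS by the moderated test of limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean, two-sided, without covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate the change of genes with low values. A ratio of mean FPKM is written as a fold. Values after ± are standard deviations for FPKM and percentages and standard errors for log2 fold changes. Single values per library were compared by an exact permutation test over the 35 assignments, whose smallest two-sided p is 0.0571.

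A set of 27 gene lists with 588 entries was fixed before the data were examined, together with the groups, the test, the rule for naming genes and the first set of other settings given below. Entries matched a rat symbol directly in 536 cases and through an older or alternative symbol in 10, 40 had no match and 2 were repeats. COL1A2 matched the symbol NEWGENE_621351. The 24 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, two-sided, Benjamini-Hochberg adjusted over the lists. The lists cover PTH receptor and cAMP machinery, the CREB and ATF family, cAMP-response and immediate early genes, stellate activation and contractile genes, quiescent stellate genes, collagens, other matrix genes, metalloproteinases and inhibitors, the TGF-beta pathway, YAP and WNT response genes, chemokines and inflammation, interferon response, cell cycle, p53 response, the unfolded protein and amino acid response, heat shock, hypoxia and glycolysis, cholesterol and lipid synthesis, autophagy and lysosome, oxidative stress response, ribosomal proteins, mitochondrial transcripts, replication-dependent histones, and markers of hepatocytes, leukocytes, endothelium and cholangiocytes.

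Genes were named by rule. Pth1r and Crebl2, from the series title, were always given. The 12 largest rises and 12 largest falls were taken among called genes with a proper symbol whose PTH values all lay above or all below the PBS values and whose mean in the higher group was at least 6.55 FPKM, the lower quartile of the tested genes. From each list up to 4 called members with the smallest p were added, or the member with the smallest p where none was called. Fos, Ier3, Btg2, Sgk1, Cxcl10, Nfkb2, Ptges, Tpm2, Acta2, Col1a1, Tgfb1, Ltbp1, Rpl15, Gnas, Hp, Tf, Cd14, Cd68, Egfl7, Sod2, Tnfaip3, Polr2h, Osmr, Ripk2, Nfkbiz, Gbp5, Cx3cl1, AABR07063424.1 and LOC102555217 lie outside the rule and were chosen after their values were seen. The values of 1 gene that the rule names are not reported here.

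The test was tried on simulated values for 10662 genes with the means and spread of these libraries and 200 changed genes. It recovered 36.0% of genes changed 1.5-fold, 78.0% of those changed 2-fold and 97.5% of those changed 4-fold, with 2, 13 and 9 false calls. The noise was drawn separately for each gene, without differences that many genes share within a library. The few false calls therefore do not give the error rate in the libraries themselves, which differed along GC content and in mitochondrial share.

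Read totals are not given in the sources used here, so the absolute depth is unknown and no counting interval was computed. Relative depth was sought in 424 genes under 0.15 FPKM, where values step by whole reads. Between 29 (PTH library 4) and 101 (PBS library 3) of them gave a usable pair with PBS library 1. Of these pairs, between 86.2% and 97.8% per library lay within 2% of a ratio of whole reads. The share that would match by chance was not computed. With PBS library 1 set to 1, PBS libraries 2 and 3 stood at 0.941 and 1.06, and PTH libraries 1 to 4 at 1.29, 1.02, 0.920 and 0.761. By this estimate, low values in PTH library 4 rest on the fewest reads.

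Other settings fixed at that time were quantile normalization, median centring, a pseudocount of 0.1, no filter, the 5331 genes with the highest means alone, a replicate block, leaving out each library, limma without the trend, sample quality weights, an absolute log2 fold change of at least 1, the sum of a symbol's rows, camera with an estimated correlation, and fry. Settings added after the data were seen were a correction for GC content, the mitochondrial share as a covariate, and genes above 0 in all libraries. For GC content, each library was corrected with a loess curve (span 0.5) on the GC content of the longest human protein-coding transcript of the matching symbol in GENCODE 29, since a rat annotation was not used here, and 9575 of the 10662 tested genes had a value. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, exact tests used scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.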

Results

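Libraries from 3 samples given PBS and 4 samples given PTH were compared. PTH acts through PTH1R, a G protein-coupled receptor that raises cAMP, and the series title links this receptor and CREBL2, a protein related to the CREB transcription factors, to liver fibrosis. The comparison asks which transcripts differ after PTH in cells labelled as the human stellate line LX2. All identifiers in the tables are rat genes, so the species of the cells is left open here and rat symbols are used. Summed FPKM ranged from 519846 to 532909 in the PBS libraries and from 472621 to 509859 in the PTH libraries. The exact permutation test gave p = 0.0571 for this difference, the smallest it can give. Per library 10589 to 10672 genes reached 1 FPKM. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

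Chemokine transcripts were lower in the PTH libraries and Crebl2 was higher. Ccl2, which attracts monocytes, stood at 1463 ± 90.8 FPKM with PBS (SD, n = 3) and 319 ± 93.5 FPKM with PTH (SD, n = 4), a 4.59-fold fall. Cxcl1, a neutrophil attractant, fell from 640 ± 45.3 to 169 ± 23.0 FPKM. Crebl2 rose from 1.21 ± 0.948 to 11.8 ± 2.37 FPKM. Collagen transcripts had a median log2 fold change of 0.48, but no single collagen gene passed the test.

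In all, 368 genes were higher and 849 lower with PTH among 10662 tested, so 30.2% of the calls were higher. That split depended on the scaling, with 664 higher and 573 lower calls after quantile normalization (53.7% higher) and 593 and 554 after median centring (51.7% higher). The counts also changed when a library was left out. Calls numbered 3 higher and 25 lower without PBS library 1, and 8 and 39 without PBS library 2. They numbered 29 and 92 without PBS library 3, 414 and 916 without PTH library 1, and 825 and 1925 without PTH library 2. Without PTH library 3 they were 14 and 69, and without PTH library 4 they were 63 and 172. Fewer libraries also weaken the test, so lost calls alone do not show that a result rests on 1 library. Without a PBS library 2305 to 2810 genes still had an unadjusted limma p under 0.05, against 3611 with all libraries. Of the 1217 called genes, 27 kept the call whichever library was left out. They include Crebl2, Ccl2, Ccl7, Ccl20, Cxcl1, Cxcl2, Cxcl3, Sod2, Tnfaip3, Egr1, Rgs2, Mt2A, Serpinb2 and Stra13.

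Pth1r, the receptor of the series title, was listed at 0 in all 7 libraries. Polr2h, a subunit of RNA polymerase that every cell needs, was likewise listed at 0 in all 7. A listed 0 alone therefore does not show that a transcript was absent. Such zeros were rare among genes in general use: 1 of 78 ribosomal, lysosomal, unfolded protein and heat shock genes was at 0 in all libraries. Over all 22062 rows, 8559 were at 0 in all libraries. The share among genes in general use need not hold for a receptor gene. Whether these cells express Pth1r remains in doubt and was not settled here. Crebl2 lay between 0.148 and 1.97 FPKM in the PBS libraries and between 9.75 and 15.2 FPKM in the PTH libraries, with a log2 fold change of 2.63 ± 0.32 (SE) and an adjusted p of 0.00755 in limma. The exact permutation test gave p = 0.0571, the smallest it can give. Crebl2 passed the test whichever library was left out, with adjusted p between 0.00591 and 0.0315. With the mitochondrial share of each library as a covariate its log2 fold change was 2.86 and its adjusted p 0.0848, within a range of 1.03e-05 to 0.0848 over all alternatives. The authors' deposited table gives Crebl2 a log2 fold change of 3.29 and an FDR of 0.0174.

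The chemokine and inflammation list fell as a group. Of its 18 tested members 16 fell, and 16 also fell adjusted over the list alone. The median log2 fold change was -1.02, and camera gave an adjusted p of 1.97e-15. With an estimated correlation of the members the call was lost (adjusted p = 0.15 with an estimated correlation). Ccl20, a lymphocyte attractant, had the largest fall of the list, at a log2 fold change of -2.49 ± 0.16 (SE). Ccl7, another monocyte attractant, fell from 146 ± 6.68 to 43.7 ± 3.56 FPKM with a limma adjusted p of 7.20e-05, and Cxcl3 fell from 137 ± 8.85 to 36.9 ± 4.37 FPKM with an adjusted p of 1.62e-04. Cxcl10, an interferon-induced chemokine, fell less, from 1439 ± 31.5 to 928 ± 56 FPKM. Nfkb2 and Ptges did not pass, with log2 fold changes of 0.06 and -0.41. The list's median difference from the PBS mean was -1.09, -1.01, -1.15 and -1.05 in PTH libraries 1 to 4. Of the 16 members, 8 kept their call without PBS library 1, 11 without PBS library 2, 13 without PTH library 3, and 15 without PBS library 3 or without PTH library 4.

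**Figure D1:**
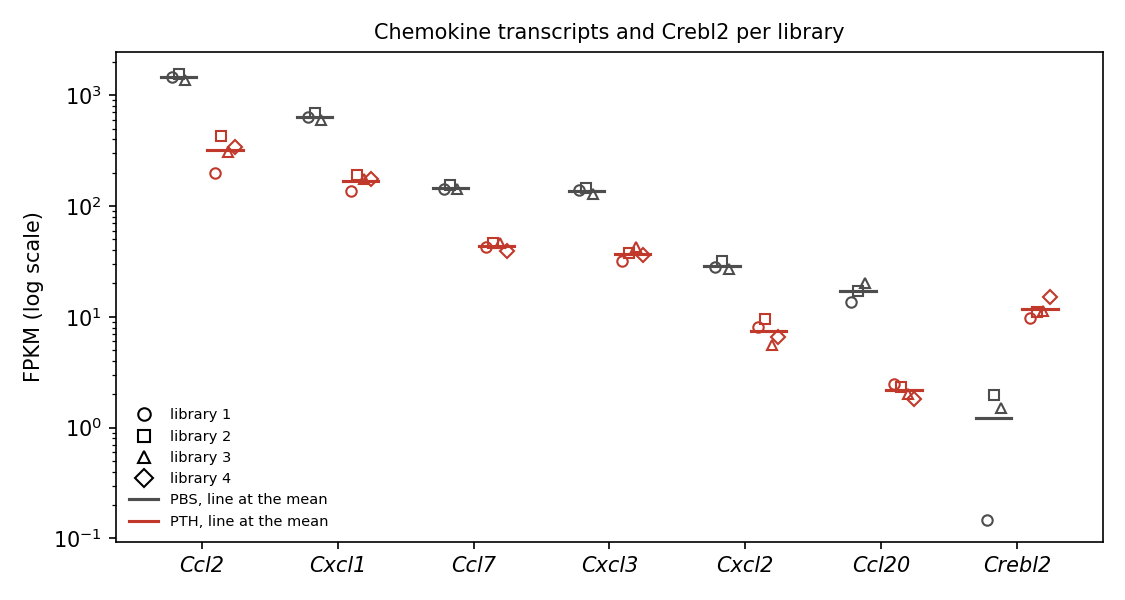
FPKM on a log scale (y axis) of 6 chemokine transcripts and Crebl2 (x axis) in each library, with PBS in grey, PTH in red, a symbol for each library number and a line at each group mean. For every chemokine shown all 4 PTH libraries lie below all 3 PBS libraries, and for Crebl2 the PTH libraries, at 9.75 to 15.2 FPKM, lie above the PBS libraries.

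Immediate early and cAMP-response genes were lower on balance. Of 25 tested members 8 fell, against 11 lower and 1 higher adjusted over the list alone. The median log2 fold change was -0.37 and camera gave an adjusted p of 0.00359 (adjusted p = 0.689 with an estimated correlation). Egr1, a growth-factor-induced transcription factor, fell from 87.5 ± 9.83 to 41.4 ± 3.63 FPKM. Rgs2, a brake on G protein signalling, fell by 0.92 on the log2 scale and Dusp1, a MAP kinase phosphatase, fell by 0.95. The other members that fell were Ier3, Btg2, Fos, Klf4 and Sgk1. The list's call was lost without PTH library 2 (adjusted p of 0.0591) and with sample quality weights (0.104), within a range of 4.62e-05 to 0.689 over all alternatives. Of the 8 members, 2 kept their call without PBS library 1, 4 without PBS library 2, 6 without PBS library 3 or PTH library 3, and 7 without PTH library 4.

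In the CREB and ATF family 4 of 22 tested members rose, and 5 rose and 1 fell adjusted over the list alone. They were Crebl2, Crebzf at a log2 fold change of 0.89 ± 0.19 (SE), Atf5 at 0.57 ± 0.12 (SE) and Creb3l1 at 0.33 ± 0.09 (SE). Camera did not call this family (median -0.08, adjusted p of 0.874), and its median and its mean of 0.11 differed in sign. Among the 27 tested members of the PTH receptor and cAMP machinery list, Pde7a, a cAMP phosphodiesterase, fell by 0.51 on the log2 scale and no other member passed. Adjusted over the list alone limma called 0 of them, while 4 higher and 1 lower had an unadjusted p under 0.05, and camera gave an adjusted p of 0.180. Gnas, which encodes the stimulatory G protein subunit, had a log2 fold change of 0.47 with an adjusted p of 0.0553. Without PBS library 1, 2 or 3, or PTH library 3 or 4, Crebl2 was the only member of these lists to keep its call.

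Of 13 tested collagen genes 12 had a log2 fold change above 0, and of 17 stellate activation and contractile genes 13 did. Limma called 0 of the collagen genes, and 0 adjusted over the list alone, while 6 had an unadjusted p under 0.05 with a higher value and 1 with a lower value. Col5a2 came closest, at 83.3 ± 6.98 FPKM with PBS and 118 ± 23.5 FPKM with PTH and an adjusted p of 0.0588. Col1a1, the main fibrillar collagen, stood at 291 and 444 FPKM (log2 fold change 0.56 ± 0.20 (SE), adjusted p of 0.0905). As a list the collagens were called higher by camera (adjusted p of 0.00977, adjusted p = 0.773 with an estimated correlation). Their median difference from the PBS mean was 0.84, 0.15, 0.49 and 0.20 in PTH libraries 1 to 4, whose mitochondrial mRNAs took 0.867, 3.61, 2.40 and 3.03% of the summed FPKM. With that share as a covariate the median turned to -0.15. The PBS shares, 5.78 to 5.90%, do not overlap those with PTH, so the covariate is hard to tell apart from PTH. Its slope rests almost wholly on the PTH libraries, and the change of sign does not show that the share explains the collagen values. Among the stellate activation and contractile genes 4 rose and 1 fell, against 5 and 3 adjusted over the list alone, with a median of 0.27 and a camera adjusted p of 0.0211 (adjusted p = 0.773 with an estimated correlation). Their median difference from the PBS mean was 0.37, 0.18, 0.28 and 0.15 in PTH libraries 1 to 4, and with the mitochondrial share as a covariate the median was 0.16 (adjusted p of 0.265). Vim, an intermediate filament, rose from 702 ± 30.5 to 928 ± 54.5 FPKM, and Ctgf, a matricellular protein gene, Tpm2 and Cald1 rose too, the last with PTH library 1 apart from the others. Acta2, the usual marker of stellate activation, stood at 0.919 and 1.59 FPKM and did not pass (adjusted p of 0.310). Both list calls ended without a filter on low values, among the 5331 genes with the highest means, after GC correction, with the mitochondrial share as a covariate and with fry, and the contractile call also after median centring, within ranges of adjusted p of 0.00202 to 0.773 for collagens and 0.0121 to 0.773 for the contractile list. Of the 5 called stellate activation and contractile genes, none kept its call without PBS library 1, 2 or 3 or PTH library 3. Without PTH library 4, 1 did, and without PTH library 1, 4 did.

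Other matrix and TGF-beta genes moved both ways. In the TGF-beta pathway 4 of 23 tested members rose and 2 fell, against 6 and 7 adjusted over the list alone (median -0.01 and mean 0.03, camera adjusted p of 0.816). Pmepa1, a TGF-beta target, rose from 11.7 ± 1.26 to 23.5 ± 3.68 FPKM, Ski, a repressor of the pathway, from 16.1 ± 1.21 to 25.2 ± 4.06 FPKM with PTH library 1 apart from the others, and Ltbp4 and Tgfb1 rose too, while the co-receptor Eng and Ltbp1 fell by 0.34 and 0.26 on the log2 scale. Of 23 other matrix genes Plod2, P4ha1 and Dcn fell and P4ha3 rose, against 5 lower and 3 higher adjusted over the list alone (median 0.03 and mean -0.01, camera adjusted p of 0.836). Limma called 0 of 6 metalloproteinases and inhibitors, with 1 at an unadjusted p under 0.05, and 1 rose adjusted over the list alone. Their camera adjusted p was 0.411, and Mmp14 had an adjusted p of 0.0523. Limma also called 0 of 11 quiescent stellate genes, with 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p of 0.922). Hand2 came first among them, at 1.70 and 0.529 FPKM (adjusted p of 0.106). Of 8 YAP and WNT response genes Cyr61 fell by 0.82 on the log2 scale and Amotl2 rose by 0.25, 1 each way adjusted over the list alone as well (camera adjusted p of 0.486). None of these calls was kept without PBS library 1 or 2, at most 1 per list without PBS library 3 or PTH library 3 or 4, and all but 1, among the other matrix genes, without PTH library 1.

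**Figure D2:**
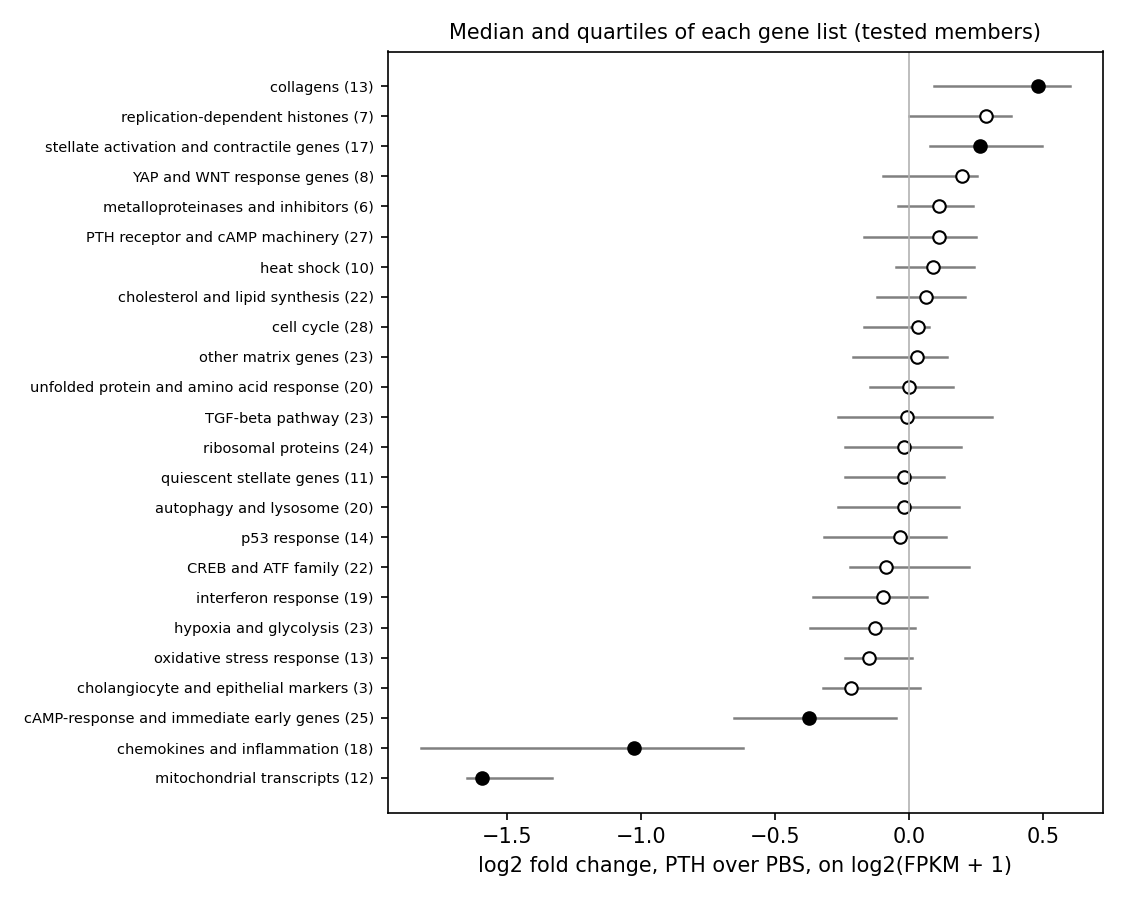
Median (point) and quartiles (line) of the log2 fold change of PTH over PBS on the log2(FPKM + 1) scale (x axis) over the tested members of each of the 24 lists (y axis, number of members in brackets), with filled points for lists called by camera at its preset correlation. Chemokines (-1.02), cAMP-response genes (-0.37) and mitochondrial transcripts (-1.59) are the lists called lower. Collagens (0.48) and stellate activation and contractile genes (0.27) are those called higher. None of these 5 lists is called with an estimated correlation (adjusted p of 0.15 for chemokines, 0.689 for cAMP-response genes and 0.773 for the others).

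Mitochondrially encoded mRNAs made up a smaller share of the PTH libraries. They took 5.85 ± 0.0616% of the summed FPKM with PBS (SD, n = 3) and 2.48 ± 1.18% with PTH (SD, n = 4), with an exact permutation p of 0.0571, the smallest possible. The share was 0.867, 3.61, 2.40 and 3.03% in PTH libraries 1 to 4. Of 12 tested mitochondrial transcripts 3 fell, against 11 adjusted over the list alone, with a median log2 fold change of -1.59 and a camera adjusted p of 2.98e-04 (adjusted p = 0.773 with an estimated correlation). Mt-nd3, a subunit of complex I, fell from 519 ± 60.2 to 184 ± 81.5 FPKM, and the cytochrome oxidase subunits Mt-co1 and Mt-co2 fell by 1.34 and 1.46 on the log2 scale. None of these 3 kept its call without PBS library 1, 2 or 3, or PTH library 3 or 4. The list's median was -1.09 without PTH library 1. The list's call also ended with fry (adjusted p of 0.137) and with the mitochondrial share as a covariate (0.761), within a range of 2.04e-08 to 0.773 over all alternatives.

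**Figure D3:**
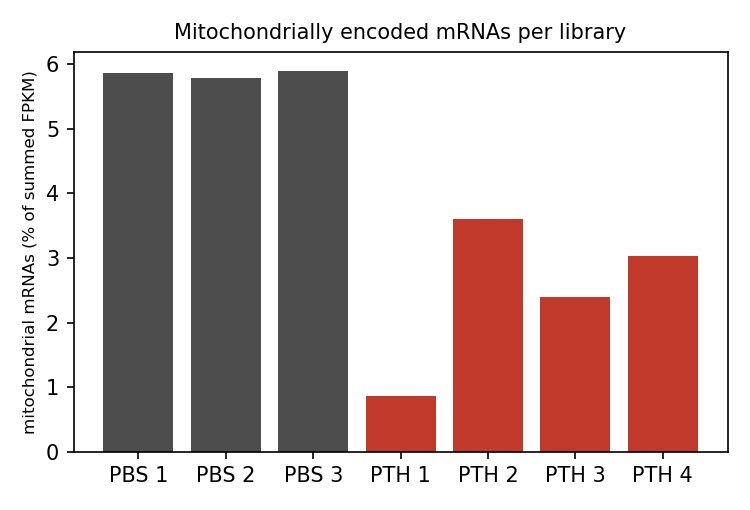
Share of the summed FPKM taken by mitochondrially encoded mRNAs (y axis, percent) in each library (x axis), PBS in grey and PTH in red. The 3 PBS libraries lie between 5.78 and 5.90%, and the 4 PTH libraries between 0.867 and 3.61%.

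The PTH libraries also differed from the PBS libraries along GC content. Across 9575 genes the log2 fold change rose with the GC content of the human counterpart transcript (Spearman correlation across genes of 0.469; genes are not independent replicates). Among the genes with the lowest GC content, 1915 in number, the median log2 fold change was -0.26 and 305 genes were lower and 12 higher, and among the 1915 with the highest GC content the median was 0.14 and 26 were lower and 144 higher. After correction for GC content 527 genes were higher and 496 lower, against 407 and 934 of the same 9575 genes without correction. The chemokine list's median was -0.93 after the correction, and that of the mitochondrial transcripts -1.43. The collagen list and the stellate activation and contractile list kept medians of 0.44 and 0.35 but not their calls (camera adjusted p of 0.0655 and 0.0769).

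**Figure D4:**
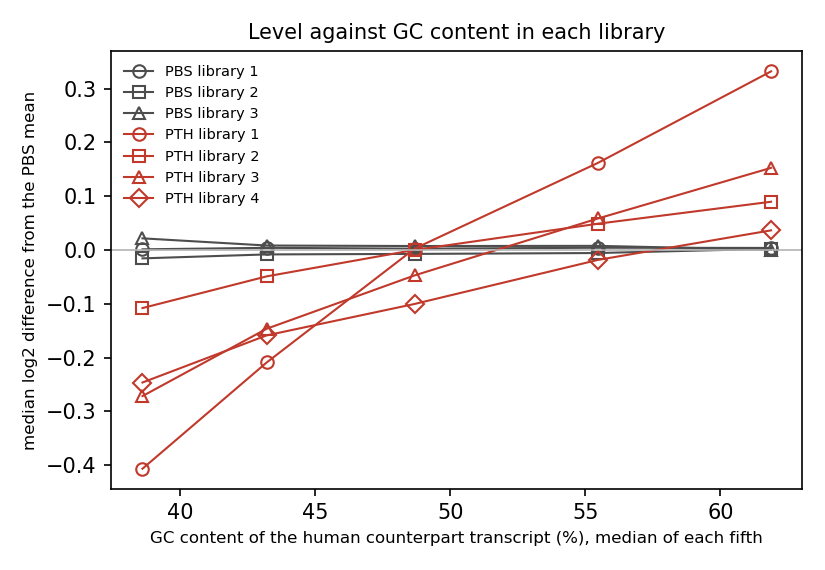
Median log2 difference from the PBS mean (y axis) against the median GC content, in percent, of the human counterpart transcript (x axis) for groups of 1915 genes ordered by GC content, with a line per library, PBS in grey and PTH in red. All 4 PTH lines climb with GC content, most steeply in PTH library 1, from -0.41 to 0.33, while the PBS lines stay close to 0.

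Among the genes the naming rule covers, the largest changes outside the chemokines were in genes of varied function. AABR07063424.1 and LOC102555217, which the rule skips because they have no proper symbol, were listed at 0 throughout a group, the former in all PTH libraries against 481 ± 23.9 FPKM with PBS and the latter in all PBS libraries against 18.8 ± 6.96 FPKM with PTH. Stra13 was listed at 0 in all PBS libraries and at 12.8 ± 5.02 FPKM with PTH. Mzt1, a microtubule-nucleation protein gene, rose, but was listed at 0 in PBS libraries 1 and 2 and at 5.26 FPKM in PBS library 3, against 5.65 to 14.6 FPKM with PTH. The genes Serf1, Hmx2, Zfp688, Dnlz, Rpp25l, Pagr1, Krt14, Mypop and Lmtk3 rose by 1.01 to 1.53 on the log2 scale. Rlim, a ubiquitin ligase gene, fell from 41.5 ± 4.16 to 3.87 ± 4.93 FPKM, with PTH libraries between 0.634 and 11.1 FPKM. Lcn2, an iron-carrier protein of inflammation, fell from 32.1 ± 1.94 to 10.03 ± 3.31 FPKM, and Serpinb2, a protease inhibitor, from 24.5 ± 2.30 to 6.67 ± 1.02 FPKM. Tnip3, an inhibitor of NF-kB signalling, Snap23, a membrane fusion protein gene, and Hmgb2l1 fell by 1.51, 1.56 and 1.68 on the log2 scale. Of the 80 named genes with a call, 12 kept it without PBS library 1, 15 without PBS library 2, 23 without PBS library 3, 75 without PTH library 1, 20 without PTH library 3 and 32 without PTH library 4.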

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

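In 88 values with 4 PTH libraries, 8 had a library whose gap to its nearest neighbour took up nearly the whole range of the group. For a single value chance gives about 1 in 20. The 88 values come from the same 4 libraries and are not independent, so their number cannot be judged against that share. No explanation was tested for these values.

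PTH library 1 stood apart in 3 genes, each time above the others. For Rpp25l it held 12.9 FPKM against 6.96 to 7.92 FPKM (gap over range 0.840), for Cald1 95.4 against 87.6 to 88.8 FPKM (0.849), and for Ski 31.2 against 22.6 to 23.5 FPKM (0.895).

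PTH library 2 stood apart in 5 genes that were lower with PTH, each time above the other PTH libraries. On the first principal component over all tested genes it was likewise the PTH library nearest the PBS libraries, at 0.0116. It held 27.5 FPKM of the interferon-induced Ifit2 against 22.9 to 23.7 FPKM (gap over range 0.836) and 23.7 FPKM of Pdk1, a regulator of pyruvate use, against 19.4 to 19.9 FPKM (0.891). For Pfkfb3, a glycolysis regulator, it held 14.9 against 13.2 to 13.4 FPKM (0.856). For the lysosomal protease Ctsl it held 323 against 268 to 277 FPKM (0.848), and for the ribosomal protein gene Rps18 896 against 598 to 622 FPKM (0.919).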

How the results depend on the processing

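The GC correction, the mitochondrial share as a covariate and the restriction to genes above 0 in all libraries were chosen after the results were seen. The numbers of genes called, 368 higher and 849 lower, moved with most settings. They were 664 higher with quantile normalization, 593 and 554 (higher and lower) with median centring, 212 and 553 with no filter on low values, which tests more genes, 184 and 441 with limma without the trend, 3109 and 4311 with sample quality weights, whose estimation stopped before it converged, and 31 and 83 with an absolute log2 fold change of at least 1. After GC correction 496 genes were lower, and with the mitochondrial share as a covariate 9 were higher and 39 lower. Leaving out each library gave 3 to 825 higher and 25 to 1925 lower genes, the lowest without PBS library 1 and the highest without PTH library 2. A replicate block over the 3 shared numbers, without PTH library 4, gave 2 higher and 17 lower genes, against 63 and 172 in those 6 libraries without the block. The deviations of libraries with the same number did not correlate (-0.0077, 0.0007 and -0.032), and no PBS library correlated best with the PTH library of its own number. These values gave no sign of a pairing. With 3 libraries per group they cannot exclude one, and the labels do not say whether the numbers pair the libraries. No named gene that was called changed direction under any setting.

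Against 2 lists higher and 3 lower, 1 list was higher with median centring, 0 with no filter, 0 among the 5331 genes with the highest means, 0 after GC correction, 0 with the mitochondrial share as a covariate, 0 with fry, and 0 higher and 0 lower with an estimated correlation. With the mitochondrial share as a covariate the median of the collagens was -0.15 and that of the mitochondrial transcripts -0.037, where camera placed the mitochondrial list above the other genes. That covariate is built from the mitochondrial transcripts, so it removes their difference by construction. Its values also do not overlap between the groups, so it is hard to tell apart from PTH, and a call lost with it is not thereby explained. The cause of the other changes was not tested. The chemokine list kept its call and a median between -1.20 and -0.93 in all settings except the estimated correlation (adjusted p of 0.15). Depth limits the genes of low level, since read totals are unknown.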

Other observations

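The test of mitochondrial mRNA levels, the use of the fit without PTH library 1 to test that library as the whole cause, the share of general genes listed at 0, the GC correction, the mitochondrial share as a covariate and the counts of genes listed at 0 in a whole group were chosen after the results were seen.

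Stress and metabolic genes outside the main themes moved in small numbers. In the oxidative stress list 3 of 13 tested members fell, against 4 lower and 1 higher adjusted over the list alone (camera adjusted p of 0.109): the metallothionein Mt2A from 582 ± 19.0 to 273 ± 29 FPKM, Prdx1, and Gclc, which starts glutathione synthesis. In the hypoxia and glycolysis list Bnip3, Pdk1 and Pfkfb3 fell among 23 tested members, and 3 fell adjusted over the list alone. Camera gave this list an adjusted p of 0.107, and 0.0384 without PTH library 1, 0.0144 after GC correction and 0.00688 with the mitochondrial share as a covariate. Of 19 interferon response genes Rsad2, Ifit2 and Ifi44 fell, against 7 adjusted over the list alone (camera adjusted p of 0.407). In the unfolded protein and amino acid list Xbp1 rose from 28.8 ± 4.68 to 45.6 ± 3.44 FPKM, Phgdh rose and Canx fell among 20 members, against 3 higher and 2 lower adjusted over the list alone (camera adjusted p of 0.744). The chaperone genes Hsp90ab1 and Hsph1 rose among 10 heat shock genes, 2 adjusted over the list alone (camera adjusted p of 0.252). With fry both the oxidative stress and the hypoxia list were called lower (adjusted p of 0.0400 and 0.0409), while camera called neither with an estimated correlation (adjusted p = 0.773 with an estimated correlation for both). Mt2A was the only gene of these 5 lists to keep its call without PBS library 1 or PTH library 3. Without PBS library 2, 1 hypoxia gene kept its call too, without PBS library 3, 1 unfolded protein gene did, and without PTH library 4, 2 interferon genes, 1 hypoxia gene and 1 unfolded protein gene did.

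Camera called none of the growth and housekeeping lists. Aurka rose and Tyms fell among 28 cell cycle genes, 1 each way adjusted over the list alone (camera adjusted p of 0.836, median 0.03 and mean -0.05). Among 14 p53 response genes Xpc and Sesn2 rose and Fas and Tnfrsf10b fell, against 2 higher and 3 lower adjusted over the list alone (0.922). Srebf1 rose and Scd fell among 22 cholesterol and lipid genes, while limma called 0 adjusted over the list alone, with 5 higher and 3 lower at an unadjusted p under 0.05 (0.252). Ctsl, Lamp2 and Gabarap fell among 20 autophagy and lysosome genes, against 4 adjusted over the list alone (0.922). Rps27a rose and Rpl30, Rps18, Rpl27 and Rpl15 fell among 24 ribosomal protein genes, against 1 higher and 5 lower adjusted over the list alone (0.922). Hist1h1b and Hist1h2bk rose among 7 replication-dependent histone genes, against 4 higher and 1 lower adjusted over the list alone (0.107). Without PBS library 1, 2 or 3 none of these calls was kept, without PTH library 3 only 1, a ribosomal protein gene, and without PTH library 4 only 2 in the p53 and 1 in the ribosomal list.

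Markers of other liver cells were scarce. Limma called 0 of 3 cholangiocyte and epithelial markers, with 1 higher and 1 lower at an unadjusted p under 0.05 and the same numbers adjusted over the list alone (camera adjusted p of 0.877), and Spp1, which stellate cells also express, stood at 342 and 295 FPKM. Of 17 hepatocyte markers 2 were tested: Hp fell from 1.95 ± 0.444 to 0.529 ± 0.367 FPKM, and Tf stood at 7.57 and 8.95 FPKM. Of 13 endothelial markers Egfl7 was tested, at 3.66 and 3.21 FPKM with PBS and PTH.

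Whether the calls could come from chance was tested by all 35 splits of the 7 libraries into 3 and 4. In 2 of the 35 splits at least 1217 genes were called, the real one included, so the share is not under 0.05 and chance is not excluded by this test. The other one set PTH library 2 with the PBS libraries and called 2125 genes, the highest of the other splits. This points to a structure of the samples in which PTH library 2 lies between the PBS libraries and the other PTH libraries. On the first principal component (45.5% of the variance) PTH library 2 stood at 0.0116, the other PTH libraries between 14.4 and 36.0 and the PBS libraries between -24.7 and -20.3.

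The fall of the chemokine and inflammation list was weighed against 3 technical explanations. A GC-linked difference between libraries and a single odd library would each need the median to move from -1.02 most of the way to 0. It was -0.93 after GC correction (SE over members 0.19, with members taken as independent) and -1.01 without PTH library 1. The correction removes only the average GC trend, whose median log2 fold change was -0.26 in the 1915 genes of lowest GC content. It could not have moved the list's median most of the way to 0. The average trend thus does not make up the fall, but a stronger GC effect on these genes is not excluded. Fewer leukocytes in the PTH cultures would need leukocyte transcripts in the PBS cultures, but of the 4 of 17 markers listed above 0, 1 reached 1 FPKM there, Cd14 at 17.4 FPKM, with Cd68 next at 0.898 FPKM. A listed 0 alone does not show absence, yet 13 of the 17 were at 0 in all libraries against 1 of 78 ribosomal, lysosomal, unfolded protein and heat shock genes. Those 78 genes are in general use, so their share need not be the share of false zeros among leukocyte markers. An effect of PTH on inflammatory transcripts is a hypothesis that stays open, as does any difference in culture or handling between the groups, for which the labels give no batch.

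The lower mitochondrial share in the PTH libraries came with the GC trend. With a GC-linked difference as the whole cause, the median would shrink towards 0. After GC correction it was -1.43, from -1.59 (SE over members 0.09). That SE takes the members as independent, though their estimated correlation was 0.989. The list's median difference from the PBS mean ran from -2.82 in PTH library 1 to -0.73 in PTH library 2. The correction removes only the average GC trend, by human GC content, and could not have removed a fall of this size. A stronger GC effect on these transcripts is not excluded. PTH library 1 as the whole cause is argued against by a median of -1.09 without it. PTH library 1 nevertheless had the lowest share and the steepest GC slope, and PTH library 2 the highest share and the least steep slope among the PTH libraries. A difference in RNA quality or library preparation that changes both may remain, and so may an effect of PTH on mitochondrial RNA. No value here decides between these.

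The rat identifiers are at odds with the human label. If human RNA had been aligned to a rat reference, the mitochondrial mRNAs, which differ strongly in sequence between these species, would be poorly counted, but their median of 1305 FPKM lay at the 99.7th percentile of the tested genes. This goes against human RNA as the source of these values but does not exclude it. The other genes would lose reads too, and the size of either loss was not measured. Mouse RNA was not weighed, though the processing notes name a mouse build. RNA of rat cells, or tables belonging to other samples than the labels describe, may explain the identifiers, and neither was tested.

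Transcripts listed at 0 throughout a group were seen in both directions. With a minimum of 5 FPKM in every library of the other group, Stra13 and LOC102555217 were seen only with PTH and AABR07063424.1 only with PBS, 3 genes in all, against at most 1 in any other split of the libraries. AABR07063424.1, a gene with no assigned name, stood at 481 ± 23.9 FPKM in the PBS libraries. In the authors' deposited table its FDR is 1, that of Stra13 is 0.0777 and that of LOC102555217 is 0.00842. Genes with a library at 0 and another of the same group at 5 FPKM or more numbered 32 within PBS and 53 within PTH.

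Of the tested genes 2483 have an FDR under 0.05 in the authors' deposited table. Of the 1217 genes called by limma 1070 are among those of the authors' deposited table, all 1070 in the same direction. Both sets of calls rest on the same libraries, so the shared direction is no independent support.

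Among the 27 genes whose call was kept whichever library was left out, 24 were lower and 3 higher, and 8 belong to the chemokine and inflammation list. Others among them that are known for roles in inflammatory signalling were Osmr, a cytokine receptor subunit at 23.1 ± 0.785 and 11.4 ± 0.773 FPKM, Ripk2, an adaptor kinase of NF-kB signalling, Nfkbiz, an NF-kB cofactor, Gbp5, an interferon-induced GTPase, and the chemokine Cx3cl1, each picked from the 27 after their values were seen. With the mitochondrial share as a covariate 48 genes were called, 9 of them in the chemokine and inflammation list.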
